A study of Mus musculus with 4 samples.

How the data were processed

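The data are 4 RNA-seq libraries of sorted mouse beta cells, 2 from CD63 high and 2 from CD63 low cells, grouped by the titles of the samples. Per the labels' protocols, islets were isolated from 10-week-old C57BL/6J males by digestion for 17 minutes at 37 °C, gradient separation and hand picking, and were cultured overnight. They were then dissociated with trypsin for 10 minutes, passed through a 35 µm mesh and sorted on CD63, and polyA RNA was amplified with a SMARTer v4 low-input kit and made into Nextera XT libraries. These libraries carry no strand information, and the labels name no molecular identifiers, so PCR copies can count as separate reads and intervals and floors cover counting error only. Low-input amplification can lose rare transcripts and can change the balance between short and long ones.

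The authors deposited 1 table of raw counts per library, with 31017 gene names, made with featureCounts 1.6.2 from a merged alignment file per the file headers. Those headers give paired-end fragment counting, grouping by gene name, no strand option, no option for reads with several alignments, and the annotation of the Cell Ranger mm10 3.0.0 reference. STAR 2.6.0c, FastQC, Cell Ranger and the mm10 build are named per the submitters' processing notes, with no role or order, and trimming is not given in the sources used here. Under these settings a read matching several places or genes is left out, which lowers the values of close paralogs (ribosomal protein genes, Ins1 and Ins2, class I genes, metallothioneins, trypsins), and reads of overlapping antisense genes cannot be told apart. Grouping by name merged 7 names that lie on more than 1 chromosome. Coordinates are those of the deposited tables, spanning the first to the last exon of a gene name.

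All 4 deposited count tables were read as they stand. Total counts were 29249270 to 35003307 per library, so 3 counts in 1 library correspond to 0.0857 to 0.103 CPM. Lower bounds of folds use 3 counts over the 2 CD63 low libraries together, 0.0433 CPM. Genes with at least 1 count numbered 16094 and 16415 in CD63 high and 15314 and 15599 in CD63 low replicates 1 and 2. The 10 most abundant genes took 57.0% and 60.4% of counts in CD63 high and 63.5% and 55.7% in CD63 low libraries, mitochondrially encoded genes 0.323% and 0.338% against 0.417% and 0.245%, and ribosomal protein genes 0.622% and 0.593% against 0.477% and 0.420%. TMM factors were 1.03 and 0.947 for CD63 high and 0.921 and 1.11 for CD63 low replicates. The shares of Gcg carry 95% Wilson intervals, and the other shares are given without. A chi-square test of counts within each group gave 37.3 (CD63 high) and 73.7 (CD63 low) per degree of freedom, so that no 2 libraries were 1 library deposited under 2 names.

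Genes were kept with filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total 15), which left 13241, scaled by TMM, and tested with glmQLFit and glmQLFTest between the groups with no other covariate. The biological coefficient of variation was 0.264 and the median standard error of a log2 fold change 0.297. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are CD63 high over CD63 low, standard errors are the size of the log2 fold change over the square root of F, and CPM values are TMM-scaled unless given as sums over a marker list, which use total counts. Of 33 gene and marker lists fixed before the data were examined, 32 had at least 3 tested members and were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 32. An estimated correlation and fry served as alternatives. With an estimated correlation camera tests on the 2 residual degrees of freedom, so almost no list could pass after adjustment. The delta cell list, for example, had a camera p of 1.52e-10 at the preset correlation and 0.0228 at an estimated one of -0.083. Missing a call under that setting thus decides nothing by itself. Only 3 lists had an unadjusted p under 0.05 there, so most did not pass before adjustment either. Camera's unadjusted p was 0.362 for ribosomal proteins, 0.536 for oxidative phosphorylation, 0.615 for the mitochondrial ribosome and 0.133 for acinar markers. Their estimated correlations were 0.908, 0.646, 0.601 and 0.797, so the p-values of such lists at the preset 0.01 may be too small. The phrase "adjusted over the list alone" means adjustment among the tested members of that list.

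Named genes followed a rule fixed before the data were examined. Cd63, Ins1, Ins2, Gcg, Sst, Ppy and Prss2 were always given. The 10 largest rises and 10 largest falls, and the 5 smallest p-values per direction, came from called genes with an average log2 CPM of at least 3, no overlap between groups and a regular symbol. Up to 4 members with the smallest p came from each list that camera called or that held a called gene. Members named beyond these, and further genes in the closing section, were chosen after their values were seen. Genes with 3 or fewer counts in a group are given with counts and no fitted fold change, and some members under this rule are left out of the text. A further 2 genes that the naming rule picked are not reported here, but stay in the fits, the counts of called genes and the list tests.

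Alternatives were other scalings (RLE factors, library size only, TMM without the 10 most abundant or without mitochondrially encoded genes), no filter or a filter of 5 CPM in 2 libraries, the replicate number in the sample titles as a block, DESeq2 1.42.0, limma-voom, a robust dispersion fit, and leaving out each library in turn. Without 1 library an arm holds a lone sample, which is assumed to vary like the other group. Each such fit called more genes than the fit of all 4 libraries, so a call kept or gained there is no evidence of a stable result. The deposited files number the CD63 low libraries 2 and 3 where the titles say 1 and 2, so by the files' numbers CD63 high replicate 2 shares its number with CD63 low replicate 1, the pairing of the crossed block. A correction for gene length and GC content, a crossed block, and list tests without marker genes of other cells were added after the data had been seen. The correction removed each library's loess trend (span 0.5) with exon length from the deposited tables and with GC content of the longest transcript per symbol in GENCODE M21, and 99.2% of tested genes had a GC value. The steps were tested on simulated data for this comparison, with 12947 genes tested. Of genes with an average log2 CPM of at least 3, 39 of 100 changed 2-fold and 98 of 100 changed 4-fold were recovered. Of 144 calls 7 were false, and 0 of 30 unchanged lists were called. Simulated genes varied independently, so this cannot show how camera at the preset correlation behaves where members move together. The estimated correlation was 0.908 for ribosomal protein genes and 0.865 for macrophage markers. Python 3.11.15 and matplotlib 3.10.9 drew the figures.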

Results

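Gene expression was measured by bulk RNA sequencing in 4 libraries of mouse pancreatic beta cells, the cells of the islets of Langerhans that make and secrete insulin. The cells came from islets of 10-week-old C57BL/6J male mice and had been sorted by flow cytometry into a CD63 high group and a CD63 low group, with 2 libraries in each. CD63 is a tetraspanin, a membrane protein of late endosomes, lysosomes and secretory vesicles. The labels call all sorted cells beta cells and name CD63 as the sorting marker, and they describe no further gate. The total counts over genes were 30436845 and 29249270 in CD63 high replicates 1 and 2, and 32953539 and 35003307 in CD63 low replicates 1 and 2. A level of 1 CPM (count-per-million) thus stood for 29.2 to 35.0 counts. Ins2 and Ins1, which encode the mouse insulins, took 49.0% and 52.2% of all counts in the CD63 high libraries and 56.4% and 48.7% in the CD63 low libraries. Across genes, which are not independent replicates, the Spearman correlation of log2 CPM was 0.975 within CD63 high, 0.976 within CD63 low and 0.948 to 0.960 between the groups.

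The transcript of the sorting marker was examined first. Cd63 (chromosome 10, 128900989 to 128912822, mm10) stood at 2026 ± 72.8 CPM in CD63 high and 1153 ± 46.9 CPM in CD63 low cells (mean ± SD, n = 2 per group). This was a 1.76-fold higher level in CD63 high cells (log2 fold change 0.81, SE 0.19). By edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p was 0.0484. Cd63 was higher in CD63 high cells in each of the 15 alternative analyses and passed 0.05 in 8 of them, with adjusted p between 0.000378 and 0.218. Without CD63 high replicate 1, CD63 high replicate 2 or CD63 low replicate 2 it was 0.0531, 0.179 and 0.0850. Since the cells had been sorted on CD63, this difference checks the groups and is not a finding about them.

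The comparison of the groups addressed how beta cells with high CD63 differ in gene expression from those with low CD63. Several transcripts each of the other islet hormones, of macrophages, of exocrine cells and of the interferon and early stress responses were higher in CD63 high cells. Glucagon transcript (Gcg) was 22.8-fold higher and the acute phase gene Lcn2 59.0-fold higher (16-fold without CD63 high replicate 1). Pf4, a chemokine gene of platelets and some macrophages, was 28.5-fold higher. Several transcripts of mature beta cells were lower in CD63 high cells, among them the glucose transporter Slc2a2 (2.86-fold), the incretin receptor Glp1r (2.57-fold) and the transcription factor Mafa (2.08-fold). Ins1 and Ins2 did not pass the test in either direction, with log2 fold changes of 0.06 (SE 0.23) and -0.06 (SE 0.23).

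edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 369 of 13241 tested genes at an adjusted p under 0.05. Of these, 331 rose and 38 fell in CD63 high cells. The rises included 265 genes that were at least 4-fold higher, against 3 falls of that size, and 40 of the genes that rose had no count in either CD63 low library. In all, 35 called genes belonged to the marker lists of other cell types, and all 35 rose. Every called gene had CPM values that did not overlap between the groups, as did 46.0% of all tested genes, where chance gives 33.3%. Without CD63 low replicate 1 the test called 769 genes (512 rose, 257 fell), and without CD63 high replicate 2, the library with the most macrophage transcripts, 450 genes (378 rose, 72 fell). With library size as the only scaling it called 67 genes (66 rose, 1 fell). In that setting 49 named genes besides Cd63 lost the call, and most of these losses are not listed gene by gene below. Labels do not say whether replicates came from separate animals or sorts, so p-values measure the spread between these libraries only, and an exact permutation of 2 against 2 libraries cannot go below a two-sided p of 0.333.

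The largest rises among well expressed genes were led by Lcn2 (chromosome 2, 32384633 to 32388252, mm10), which encodes lipocalin 2, an iron-binding acute phase protein. It reached 501 and 78.5 CPM in the CD63 high libraries against 6.95 and 2.95 CPM in the CD63 low libraries (log2 fold change 5.88, SE 0.78, edgeR adjusted p 0.00384). Lrg1, another acute phase gene, followed with a log2 fold change of 5.26 (SE 0.82). Pf4, a chemokine of platelets and some macrophages, rose by 4.83 (SE 0.34, edgeR adjusted p 0.000175). The other 7 of these 10 genes were Gcg and 6 genes known from macrophages and other myeloid cells: Lyz2, Cd53, Pla2g7, Gpnmb, Ms4a6d and Tyrobp, with log2 fold changes of 4.35 to 4.52. Among the smallest p-values stood Gpx3, a secreted glutathione peroxidase (log2 fold change 3.09, SE 0.26), the serine protease inhibitor Serpina3n (3.09, SE 0.28) and Spp1, osteopontin (3.57, SE 0.34), each with an edgeR adjusted p under 0.001. Leaving out 1 library moved several log2 fold changes. Without CD63 high replicate 1 those of Lcn2, Lrg1 and Spp1 were 4.0, 4.01 and 2.89, and without CD63 high replicate 2 those of Lyz2, Cd53, Pla2g7, Gpnmb, Ms4a6d and Tyrobp were 2.69, 3.42, 3.40, 2.42, 3.39 and 3.13. The highest values were 6.67 for Lcn2 (without CD63 high replicate 2), 7.48 for Lrg1 (without CD63 low replicate 1), 5.13 for Cd53 (without CD63 high replicate 1), and 5.50 for Lyz2, 5.78 for Pla2g7, 7.12 for Gpnmb and 5.99 for Tyrobp (without CD63 low replicate 2). A robust fit of the dispersion ended the calls of Lcn2, Lrg1, Lyz2, Pla2g7, Gpnmb and Tyrobp (edgeR adjusted p 0.0553 to 0.491). The CD63 high libraries of these genes lay far apart, but so did those of Cd53 and Ms4a6d, which kept the call. The calls of Lyz2 and Tyrobp also ended with limma-voom (adjusted p 0.0500 and 0.0529), and that of Gpnmb with limma-voom (0.145), DESeq2 (0.149) and the length and GC correction (0.0567).

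The falls were smaller. Among called genes with an average log2 CPM of at least 3, Insrr, the insulin receptor-related receptor (chromosome 3, 87796951 to 87816101, mm10), fell the most, from 110 ± 23.5 to 32.8 ± 0.249 CPM (mean ± SD, n = 2), with a log2 fold change of -1.75 (SE 0.22). Its edgeR adjusted p was 0.00331. Next came the potassium chloride cotransporter Slc12a7 (-1.58, SE 0.30), Cib3 (-1.52, SE 0.32), Slc2a2 (-1.51, SE 0.23) and Hspa12a (-1.48, SE 0.30). Tmod1, Cabp7, Glp1r, Slc30a8 and Zbtb14 completed the 10 largest falls at this level of expression, at -1.43 to -1.33, and the ligand Wnt4 (-1.28, SE 0.21) was among the 5 with the smallest p. Hspa12a and Tmod1 lost the call without CD63 high replicate 2 (edgeR adjusted p 0.0528 and 0.169) and without CD63 low replicate 2 (0.0604 and 0.0962), Tmod1 also with limma-voom, the robust fit and the length and GC correction (0.0521, 0.0585 and 0.0538), and Cib3 without CD63 high replicate 1 (0.0584). With library size as the only scaling all of these 10 largest falls lost the call (edgeR adjusted p 0.0504 to 0.182), while Wnt4 kept it. Slc12a7 was at -0.99 without CD63 low replicate 2. The 3 falls of at least 4-fold, Cdh22 (-2.07, SE 0.36), Pcdhb9 and Gm5464, lay below that level of expression and are named after their values were seen.

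**Figure D1:**
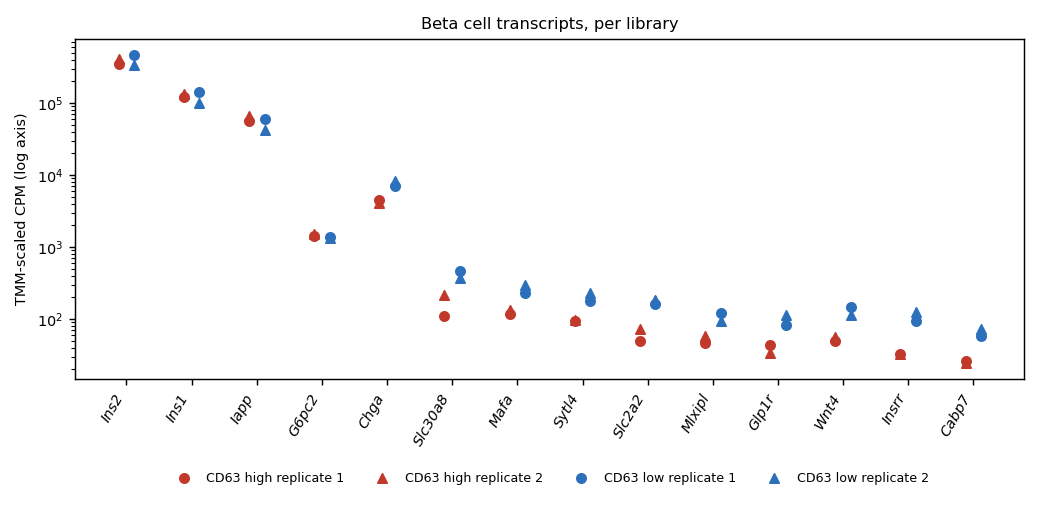
Transcript levels of 14 beta cell genes in each library, as TMM-scaled CPM on a log axis, with CD63 high libraries in red and CD63 low libraries in blue, circles for replicate 1 and triangles for replicate 2. Ins2, Ins1, Iapp and G6pc2 overlapped between the groups or differed by less than the test could call, whereas Slc30a8, Mafa, Sytl4, Slc2a2, Mlxipl, Glp1r, Wnt4, Insrr and Cabp7 lay lower in both CD63 high libraries and passed the test.

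Beta cell maturity genes were lower in CD63 high cells. Of 17 tested members, 5 fell and none rose over all genes tested, and 11 fell adjusted over the list alone, with a median log2 fold change of -0.75. The 5 were Slc2a2, the main glucose transporter of mouse beta cells, Glp1r, the receptor of glucagon-like peptide 1, Slc30a8, the zinc transporter of insulin granules, Sytl4, a granule docking protein, and Mafa, an activator of insulin transcription. Slc2a2 (chromosome 3, 28697903 to 28731359, mm10) stood at 61.0 ± 15.5 CPM in CD63 high and 174 ± 14.3 CPM in CD63 low cells (mean ± SD, n = 2). Ucn3, a peptide of mature beta cells (log2 fold change -0.82), missed the threshold with an edgeR adjusted p of 0.0812. With library size as the only scaling all 5 called members lost the call (edgeR adjusted p 0.0541 to 0.122). By camera, a competitive gene set test, the list was lower with an adjusted p of 1.17e-08 at the preset correlation of 0.01, and the adjusted p was 0.297 with an estimated correlation. The calls of Slc30a8 and Mafa ended without CD63 high replicate 1 (edgeR adjusted p 0.0731 and 0.0760), and that of Slc30a8 also in the robust fit (0.0515). Part of the marker transcripts of alpha, delta, gamma, acinar, duct and macrophage cells were higher in the same libraries, for alpha and duct cells 2 of 11 each.

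The lists of beta cell transcription factors and of stimulus-secretion coupling had negative medians, with few members past the threshold. In the same CD63 high libraries, part of the markers of alpha, delta, gamma, acinar, duct and macrophage cells were higher. Among 26 tested transcription factors, Mafa and Mlxipl, the carbohydrate response element binding protein, fell and Nr4a1 rose, and 23 did not pass (median log2 fold change -0.32; 3 fell and 1 rose adjusted over the list alone). Camera gave the list an adjusted p of 0.000547, and 0.297 with an estimated correlation. Pdx1 (-0.58) and Nkx6-1 (-0.55) did not pass, with edgeR adjusted p of 0.173 and 0.179. The calls of Mlxipl and Nr4a1 ended without CD63 high replicate 1 (edgeR adjusted p 0.154 and 0.0691), where Nr4a1 was at 1.49, against 2.14 with all libraries and 2.76 without CD63 low replicate 2. That of Mlxipl also ended with the length and GC correction (0.133) and that of Nr4a1 with limma-voom (0.0518). Of 30 stimulus-secretion coupling and exocytosis genes 1 fell, Glp1r, and 27 had log2 fold changes below 0 (median -0.39; 2 fell adjusted over the list alone). Its camera adjusted p was 3.18e-05, and 0.297 with an estimated correlation. Gipr (-0.85), Trpm5 (-0.98) and Cadps (-0.74), involved in incretin sensing, membrane depolarisation and vesicle priming, did not pass, and passed in 3, 5 and 0 of 15 alternatives.

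Insulin granule and peptide processing genes went both ways. Vgf, a granule protein, rose (log2 fold change 2.34, SE 0.38, and 3.05 without CD63 low replicate 2), Slc30a8 and Sytl4 fell, and 23 of the 26 members did not pass. Adjusted over the list alone, 3 rose and 3 fell. Its median and mean log2 fold change, 0.05 each, lay above 0 while camera's direction was down, with an adjusted p of 0.876. Chga, chromogranin A, stood at 4318 ± 321 CPM in CD63 high and 7760 ± 937 CPM in CD63 low cells (mean ± SD, n = 2), and its edgeR adjusted p of 0.0518 missed the threshold, whereas DESeq2 (adjusted p 0.000584), limma-voom (0.0335) and the length and GC correction (0.0241) called it.

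Part of the genes of immaturity, dedifferentiation and those usually silenced in adult beta cells were higher in CD63 high cells. Of 22 tested members, 5 rose and none fell, and 11 rose adjusted over the list alone (median log2 fold change 1.70, also with the 2 genes without counts in CD63 low held at their lower bound). Ldha, lactate dehydrogenase A, rose from 1.39 ± 0.550 to 24.9 ± 22.5 CPM (mean ± SD, n = 2; log2 fold change 4.17, SE 0.63), and Rbp4, retinol binding protein 4, by 2.58 (SE 0.36). Ldha was at 2.70 without CD63 high replicate 2 and 4.89 without CD63 high replicate 1, and Rbp4 at 3.33 without CD63 low replicate 1. The call of Ldha ended with limma-voom (adjusted p 0.0528) and in the robust fit (0.0904), and that of Mgst1 with limma-voom (0.0563). The other 3 were near the floor in CD63 low cells: Mgst1, Igfbp4 and the hexokinase Hk1 had 219, 104 and 68 counts over the CD63 high libraries and 6, 1 and 0 over the CD63 low libraries. Camera gave the list an adjusted p of 8.08e-11, and 0.297 with an estimated correlation. Ldha is also expressed in macrophages and Rbp4 is a delta cell marker, and markers of both cell types rose in the same libraries. Genes proposed as markers of beta cell subpopulations included 6 that rose, Sst, Cd24a, Rbp4, Cd36, Cd9 and Cd63 itself, and 1 that fell, Mlxipl, among 18 tested, with 7 rising and 3 falling adjusted over the list alone. Camera gave an adjusted p of 0.000178, against 0.422 with an estimated correlation and 0.0667 once marker genes of other cell types were left out of the list. Cd63, on which the cells were sorted, stayed in the list in each of these tests, so they rest in part on the sort. The call of Cd36 ended with limma-voom (adjusted p 0.0575) and in the robust fit (0.105).

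**Figure D2:**
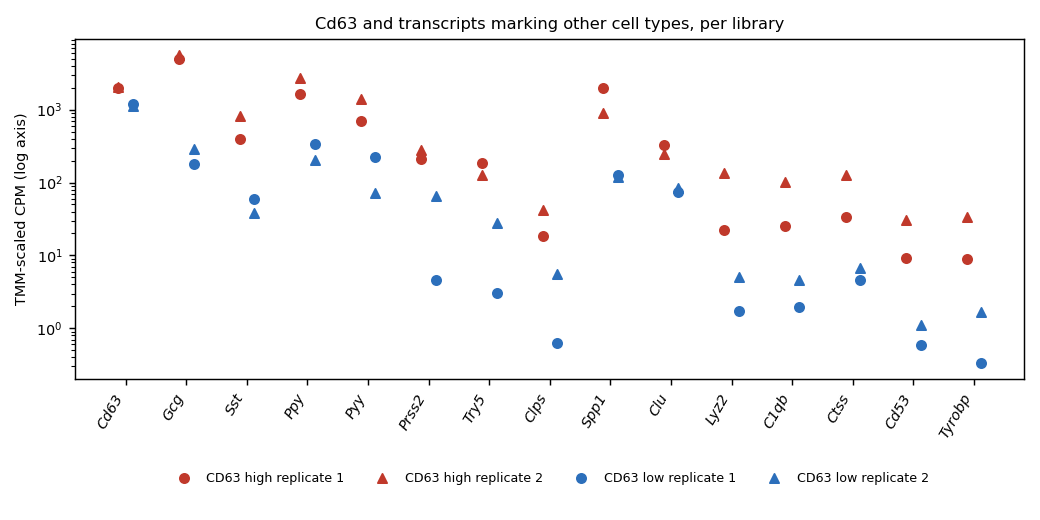
Levels of Cd63 and of 14 marker transcripts of other pancreatic and immune cells in each library, as TMM-scaled CPM on a log axis, with CD63 high libraries in red and CD63 low libraries in blue, circles for replicate 1 and triangles for replicate 2. Every transcript shown lay higher in both CD63 high libraries than in either CD63 low library, Prss2 did not pass the test, and Lyz2, C1qb, Ctss, Cd53 and Tyrobp lay several-fold higher in CD63 high replicate 2 than in replicate 1.

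Hormone transcripts of the other islet endocrine cells rose together. Gcg, the alpha cell hormone gene (chromosome 2, 62474530 to 62483650, mm10), stood at 5316 ± 466 CPM in CD63 high and 233 ± 76.3 CPM in CD63 low cells (mean ± SD, n = 2; log2 fold change 4.51, SE 0.28). Its edgeR adjusted p of 0.000103 was the smallest of all genes. Gcg took 0.513% and 0.534% of counts in CD63 high replicates 1 and 2 (95% Wilson intervals 0.511 to 0.516% and 0.532 to 0.537%) and 0.0165% and 0.0320% in CD63 low replicates 1 and 2 (0.0161 to 0.0170% and 0.0314 to 0.0326%). Sst, somatostatin of delta cells, reached 401 and 819 CPM in CD63 high against 59.6 and 38.0 CPM in CD63 low libraries (log2 fold change 3.65, SE 0.36, and 3.04 without CD63 high replicate 2). Ppy, pancreatic polypeptide of gamma cells, reached 1631 and 2730 CPM against 337 and 206 CPM (3.01, SE 0.31).

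In the marker lists of these cells, 2 of 11 alpha cell genes (Gcg and Gc), 3 of 4 delta cell genes (Sst, Rbp4 and Hhex) and 3 of 5 gamma cell genes (Ppy, Pyy and Cartpt) rose and none fell. Adjusted over the list alone, 4 alpha cell genes rose and 2 fell, and 3 delta and 3 gamma cell genes rose. For the 3 lists camera gave adjusted p of 1.38e-05, 8.12e-10 and 2.48e-06, and 0.297 for each with an estimated correlation. The call of Cartpt ended without CD63 high replicate 1 (edgeR adjusted p 0.119), with limma-voom (0.0523) and with the length and GC correction (0.0567), that of Hhex with limma-voom (0.0635) and that of Pyy in the robust fit (0.230). The delta cell median of 3.11 was 4.07, 4.49 and 4.94 without CD63 high replicate 1, CD63 low replicate 1 and CD63 low replicate 2.

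Exocrine transcripts were higher as well. Of 20 tested acinar cell genes 6 rose (Rnase1, Zg16, Try5, Clps, Cpa1 and Reg1), none fell, and 17 rose adjusted over the list alone, with a median log2 fold change of 2.56. That median was 1.69 without CD63 low replicate 1, 5.39 without CD63 low replicate 2 and 1.96 without CD63 high replicate 2. DESeq2 called 1 of the 20 genes and limma-voom 11. The calls of Zg16, Try5 and Clps ended with DESeq2 (adjusted p 0.0534, 0.153 and 0.200), the robust fit (0.191, 0.483 and 0.429) and the length and GC correction (0.0568, 0.125 and 0.143), and that of Zg16 with limma-voom (0.120). Camera called the list higher with an adjusted p of 1.72e-18, and 0.344 with an estimated correlation. The gap in its mean log2 CPM between the 2 CD63 low libraries, 3.16, was nearly as large as the difference between the groups (3.18). Prss2, trypsin 2, read 209 and 283 CPM in CD63 high libraries and 4.58 and 66.4 CPM in CD63 low libraries, and did not pass (log2 fold change 2.79, SE 0.81, edgeR adjusted p 0.108). It passed in 7 of 15 alternatives, among them limma-voom (adjusted p 0.0284), the replicate block (2.26e-16) and each left-out library, a setting that calls genes more readily. Its log2 fold change ran from 1.89 without CD63 low replicate 1 to 5.76 without CD63 low replicate 2. Summed acinar markers came to 1240 and 1815 CPM in CD63 high against 81.9 and 563 CPM in CD63 low libraries. Spp1 and Clu (clusterin; 1.84, SE 0.22), listed as duct cell genes, rose among 11 tested, none fell, and 4 rose adjusted over the list alone, with a camera adjusted p of 1.71e-06, and 0.297 with an estimated correlation. Trypsin genes are close paralogs, so single values of Prss2 and Try5 are uncertain.

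Macrophage and dendritic cell markers were higher in CD63 high cells. Of 23 tested, 17 rose and none fell, 21 rose adjusted over the list alone, and the median log2 fold change was 3.60. C1qb of the complement C1q complex rose by 4.27 (SE 0.61), the lysosomal protease Ctss by 3.84 (SE 0.52) and Laptm5 by 3.60 (SE 0.48). Without CD63 high replicate 2 these were 2.96, 2.58 and 2.63 and the list median 2.32, and without CD63 high replicate 1 C1qb and Ctss were 4.95 and 4.50 and the median 4.29. C1qb was 5.04 without CD63 low replicate 2. The robust fit ended the calls of C1qb and Ctss (edgeR adjusted p 0.222 and 0.155). The camera adjusted p was 7.45e-34, and 0.297 with an estimated correlation. Summed over the list, markers came to 430 and 1801 CPM in CD63 high replicates 1 and 2, against 67.7 and 132 CPM in CD63 low replicates 1 and 2. Apoe and Cd74 were the most abundant, at 298 and 259 CPM on average in CD63 high and 20.5 and 22.7 CPM in CD63 low cells.

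Other marker lists held few tested genes. Ccl5 rose (log2 fold change 4.46, SE 0.63; 3.18 without CD63 high replicate 2 and 5.13 without CD63 high replicate 1) among 3 lymphocyte genes, and 1 of 4 stellate cell, fibroblast or pericyte genes rose (Sparc, with 158 counts over the CD63 high and 3 over the CD63 low libraries), with the same counts adjusted over the list alone. With limma-voom the calls of Ccl5 and Sparc ended (adjusted p 0.0591 and 0.0673), and that of Sparc also without CD63 high replicate 2 (0.0935). These lists had camera adjusted p of 0.0477 each, and 0.384 and 0.514 with an estimated correlation. Both calls ended without CD63 high replicate 2 (adjusted p 0.133 and 0.271), the lymphocyte call also without CD63 low replicate 1 (0.0501), and the stellate call without CD63 low replicate 2 (0.0975). The length and GC correction ended both (0.131 and 0.0574), library size only the lymphocyte call (0.0551), and the replicate block and leaving out the 10 most abundant genes the stellate call (0.0559 and 0.0557). Over the alternatives with the preset correlation the adjusted p ran from 0.00171 to 0.133 and from 2.53e-06 to 0.271. None of 5 endothelial and 4 Schwann cell or neuron genes passed in edgeR, DESeq2 or limma-voom, or adjusted over the list alone, and 1 and 0 of them had an unadjusted edgeR p under 0.05. Camera did not call either list (adjusted p 0.584 and 0.224), although without CD63 high replicate 2 the endothelial list was higher (0.0261). Erythrocyte genes summed to 0.274 to 0.789 CPM and had no tested member.

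**Figure D3:**
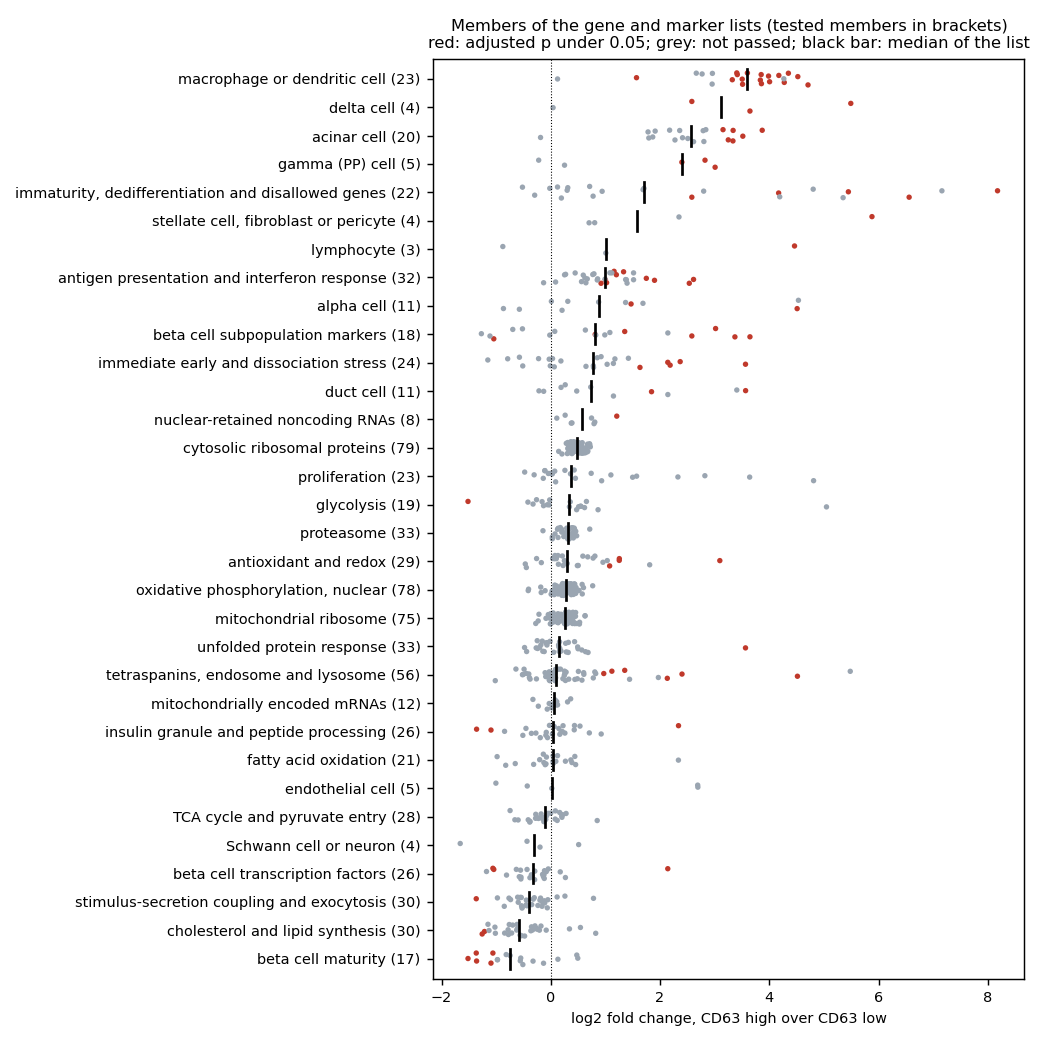
Log2 fold change, CD63 high over CD63 low, of each tested member of the 32 lists, sorted by list median (black bar), with the number of tested members in brackets. Red points passed an adjusted p of 0.05 and grey points did not; with all 4 libraries, macrophage, delta, acinar and gamma cell markers had the highest medians, from 2.40 to 3.60, an order that changed when a library was left out (the stellate median was 6.06 without CD63 low replicate 1), and beta cell maturity genes the lowest, at -0.75.

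Antigen presentation and interferon response genes were higher in CD63 high cells. Of 32 tested members, 10 rose and none fell, 23 rose adjusted over the list alone, and the median log2 fold change was 1.00. B2m, the light chain of major histocompatibility class I, rose from 207 ± 82.9 to 771 ± 105 CPM (mean ± SD, n = 2; log2 fold change 1.90, SE 0.27). Isg15, an interferon-induced ubiquitin-like protein (2.61, SE 0.40, and 1.73 without CD63 high replicate 1), Bst2 (1.75, SE 0.25) and Xaf1 (1.16, SE 0.22) rose too. The camera adjusted p was 1.72e-18, and 0.344 with an estimated correlation. The call of Xaf1 ended without CD63 high replicate 1 (edgeR adjusted p 0.0832). Macrophage markers, which rose in the same libraries, were higher in CD63 high replicate 2 than in replicate 1, whereas 27 of the 29 members of this list above 5 CPM were lower in replicate 2. Class I heavy chain genes are close paralogs and their single values are uncertain.

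Immediate early and stress response genes rose in part. Among 24 immediate early and dissociation stress genes 5 rose (Fos, Ier2, Ier3, Atf3 and Nr4a1), none fell, and 11 rose adjusted over the list alone, with a median log2 fold change of 0.78. Fos, a subunit of the AP-1 transcription factor, rose from 8.32 ± 0.947 to 43.0 ± 22.9 CPM (mean ± SD, n = 2; log2 fold change 2.37, SE 0.35; 1.68 without CD63 high replicate 1). By camera the adjusted p was 2.48e-06, and 0.297 with an estimated correlation. Of 29 antioxidant genes 4 rose, Gpx3, the metallothioneins Mt1 (1.08, SE 0.20) and Mt2 (1.25, SE 0.20), and the heme oxygenase Hmox1 (1.25, SE 0.26). None fell, and 9 rose adjusted over the list alone (camera adjusted p 1.71e-06, and 0.344 with an estimated correlation). Without CD63 high replicate 2 the calls of Mt1 (edgeR adjusted p 0.0510) and Hmox1 (0.206) ended, and that of Hmox1 also with the length and GC correction (0.0572). In the unfolded protein response list 1 of 33 genes rose, Atf3 (3.56, SE 0.54), also adjusted over the list alone, and camera did not call it (adjusted p 0.170), except without CD63 low replicate 2 (0.0394), while fry called it for change in either direction (0.0128). Macrophage and exocrine markers rose in the same libraries. Hmox1, at 83.1 and 145 CPM in CD63 high replicates 1 and 2, was higher in replicate 2, as macrophage and most acinar markers were.

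Lysosomal proteases made up most of the called genes in the list of tetraspanins, endosome and lysosome. Ctsz (log2 fold change 2.13, SE 0.22), Lgmn (2.40, SE 0.28), Ctsb (1.12, SE 0.21), Ctsl, Cd9 and the leukocyte tetraspanin Cd53 (4.51, SE 0.57) rose among 56 members. None fell, 50 did not pass, and 11 rose adjusted over the list alone. The median log2 fold change was 0.09. The camera adjusted p was 0.000610, and 0.502 with an estimated correlation, and without CD63 high replicate 2 it was 0.112 (6.18e-05 to 0.112 over the alternatives with the preset correlation). Without that library the edgeR adjusted p of Ctsb was 0.0830. These proteases are also abundant in macrophages, whose markers were highest in that library.

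The cholesterol and lipid synthesis list had a negative median, with 2 members past the threshold. Insig1, a sterol-regulated brake on this pathway (log2 fold change -1.21, SE 0.23), and the desaturase Scd2 (-1.26, SE 0.24) fell among 30 tested, none rose, and 8 fell adjusted over the list alone, with a median log2 fold change of -0.59. By camera the list was lower with an adjusted p of 5.45e-07, and 0.464 with an estimated correlation. The gap in its mean log2 CPM between the 2 CD63 low libraries, 0.49, was as large as the difference between the groups (-0.48). The call of Insig1 ended without CD63 high replicate 1 (edgeR adjusted p 0.0504).

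Ribosomal, mitochondrial and proteasome genes had small, mostly positive log2 fold changes without a single gene past the threshold in edgeR. All 79 cytosolic ribosomal protein genes had log2 fold changes above 0, with a median of 0.48 (1.39-fold), as did 73 of 78 nuclear genes of oxidative phosphorylation (0.28), 66 of 75 mitochondrial ribosome genes (0.26) and 32 of 33 proteasome genes (0.31). None passed in edgeR, also adjusted over the list alone, while 31, 8, 4 and 3 had an unadjusted p under 0.05. DESeq2 called 2, 1, 0 and 1 of them and limma-voom none. The camera adjusted p was 9.59e-13, 0.000160, 0.00413 and 0.000627, against 0.514, 0.660, 0.678 and 0.514 with an estimated correlation. Without CD63 high replicate 2 or CD63 low replicate 2 the oxidative phosphorylation call ended (0.0786 and 0.495), and so did that of the mitochondrial ribosome (0.340 and 0.576). The length and GC correction ended both as well (0.120 and 0.131), with means of 0.13 instead of 0.26 and 0.14 instead of 0.22. Between the 2 CD63 low libraries, mean log2 CPM differed by 0.51 (ribosomal proteins), 0.37 (oxidative phosphorylation), 0.27 (mitochondrial ribosome) and 0.16 (proteasome). The differences between the groups were 0.50, 0.27, 0.22 and 0.29 in the same order. Over the alternatives with the preset correlation the camera adjusted p of oxidative phosphorylation ran from 2.23e-09 to 0.495. That of the mitochondrial ribosome ran from 4.33e-05 to 0.576. Ndufc2 of complex I came closest, at 320 ± 5.88 against 188 ± 32.2 CPM (mean ± SD, n = 2), and its edgeR adjusted p was 0.0754 (0.00535 with DESeq2 and 0.0174 without CD63 low replicate 1).

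Camera did not call the remaining energy metabolism lists, while fry called glycolysis and fatty acid oxidation for change in either direction (adjusted p 0.0387 and 0.0494). Of 12 mitochondrially encoded mRNAs none passed in edgeR, DESeq2 or limma-voom, or adjusted over the list alone, and none had an unadjusted p under 0.05 (median log2 fold change 0.06, camera adjusted p 0.876). Leaving out CD63 low replicate 1 gave a higher list (0.60, adjusted p 0.00274) and leaving out CD63 low replicate 2 a lower one (-0.38, 0.00755). Among 28 genes of the tricarboxylic acid cycle (camera adjusted p 0.235) and 21 of fatty acid oxidation (0.811) none passed in edgeR, also adjusted over the list alone. An unadjusted p under 0.05 was found for 3 genes in each, and DESeq2 called 1 in each and limma-voom 1 and 0. The fatty acid oxidation median and mean (0.04 and 0.05) lay above 0 while camera's direction was down. In edgeR, glycolysis held 1 of 19 genes past the threshold, Slc2a2, which fell, with 4 rising and 1 falling adjusted over the list alone (camera adjusted p 0.195), while DESeq2 called 4 and limma-voom 1. Gapdh read 438 ± 27.3 CPM in CD63 high and 285 ± 9.81 CPM in CD63 low cells (mean ± SD, n = 2), which missed the threshold over all genes in edgeR (adjusted p 0.127) and passed in DESeq2 (0.0229).

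Among 8 nuclear-retained noncoding RNAs, Neat1 rose (log2 fold change 1.21, SE 0.25) and 2 rose adjusted over the list alone, with a camera adjusted p of 0.0155, and 0.480 with an estimated correlation. Malat1, at 1294 ± 135 against 748 ± 205 CPM (mean ± SD, n = 2), did not pass in edgeR (adjusted p 0.106) but did in DESeq2 (0.0118) and without CD63 low replicate 1 (0.00527). The list's call ended without CD63 high replicate 1 (0.188) and without CD63 low replicate 2 (0.178), with 0.00184 to 0.188 over the alternatives with the preset correlation, and that of Neat1 without CD63 high replicate 1 (edgeR adjusted p 0.148). None of 23 proliferation genes passed in edgeR, DESeq2 or limma-voom, or adjusted over the list alone, and 3 had an unadjusted edgeR p under 0.05. Camera gave that list an adjusted p of 0.0448, against 0.400 with an estimated correlation, 0.487 without CD63 high replicate 1 and 0.0574 with the length and GC correction (0.000422 to 0.878 over the alternatives with the preset correlation). In all, camera called 24 of 32 lists at the preset correlation, 20 higher and 4 lower. With an estimated correlation, a test that 2 residual degrees of freedom left with little power, it called 0, with 3 lists at an unadjusted p under 0.05. The self-contained test fry called 2 for change in 1 direction and 11 for change in either direction. In neither form did it call the macrophage (fry adjusted p 0.244 and 0.168), acinar (0.244 and 0.168), interferon (0.241 and 0.142), delta cell (0.150 and 0.0697) or ribosomal protein list (0.254 and 0.197). The maturity list was called by fry only for change in either direction (0.0494, against 0.104 in 1 direction).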

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

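The length and GC correction, the crossed block and the list tests without marker genes were chosen after the data had been seen. The other alternatives were fixed before the data were examined. Every gene called both in the edgeR analysis and under an alternative kept its direction, with 208 to 369 shared calls under all alternatives except library size only, where all 67 were shared. The count of 369 genes lay between 248 and 401 with RLE factors, without the 10 most abundant or the mitochondrially encoded genes, with the stricter filter, limma-voom, the robust fit, and the length and GC correction. It was 67 (66 rose, 1 fell) with library size only, 940 (690 rose, 250 fell) without a filter, where 18371 genes were tested, and 684 (538 rose, 146 fell) with DESeq2, and the cause was not tested. Leaving out 1 library gave 450 genes (without CD63 high replicate 2) to 769 genes (without CD63 low replicate 1), and 516 and 527 without CD63 high replicate 1 and CD63 low replicate 2. Samples with the same number in their titles deviated from their group means with a correlation across genes of -0.101, of opposite sign in the crossed pairing, which joins the 2 libraries with a shared number in the deposited files. As these numberings disagree, neither was taken as pairs. The replicate block gave 616 genes (535 rose, 81 fell) and left Cd63 at 0.81 with an adjusted p of 0.218. The crossed pairing gave 942 genes (607 rose, 335 fell). Cd63 stayed positive but missed the threshold with library size only (log2 fold change 0.77, adjusted p 0.113), the stricter filter (0.85, 0.0512) and the robust fit (0.81, 0.0523), and ran from 0.78 to 0.85 over the left-out libraries. In the preset camera test 24 lists were called, against 19 to 24 under other scalings, filters, corrections and left-out libraries, 0 with an estimated correlation, and 2 and 11 in the directional and mixed forms of fry. With the preset correlation, 16 of the 24 called lists kept the call under every alternative and 8 lost it at least once. Of 69 called named genes besides Cd63, 0 changed sign and 37 kept the call under every alternative with a value except library size only, where 49 lost it. Reversals occurred only among results that did not pass, besides the proliferation list, and their causes were not tested. The insulin granule list turned to camera's upward direction without the 10 most abundant genes (median 0.0971), with the stricter filter (0.0806), in both forms of fry (0.0462) and without CD63 high replicate 2 (-0.00573), and its median ran from there to 0.0305 over the left-out libraries. The proliferation list turned down with the stricter filter (median 0.0268). The length and GC correction turned Ins1 (-0.18) and the mitochondrially encoded mRNAs (-0.16). Over the left-out libraries, Ins1 ran from -0.15 to 0.33, Ins2 from -0.26 to 0.20, Col1a2 from -0.78 to 1.42, Acta2 from -0.22 to 6.47, the mitochondrially encoded mRNAs from -0.38 to 0.60 and the endothelial list from -0.38 to 3.97. At this depth and spread, simulated 2-fold changes were recovered for 39 of 100 genes and 4-fold changes for 98 of 100, so smaller changes can be missed. These genes had an average log2 CPM of at least 3, and recovery below that level was not simulated.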

Other observations

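The tests of spread between libraries, of dilution, of the counts outside the most abundant genes and of macrophages, and the genes named in the next paragraph, were chosen after the results had been seen, and the length and GC correction was added after the data had been seen.

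Among inflammatory and acute phase genes, which formed no fixed list and were not tested as a group, several were higher in CD63 high cells, in the same libraries in which macrophage markers rose. Saa3 (serum amyloid A3) and Slpi (a secreted protease inhibitor) had 683 and 661 counts over the CD63 high libraries and 0 in both CD63 low libraries, and were at least 261-fold and 264-fold higher against a floor of 3 counts over the CD63 low group (0.0433 CPM). Against the same floor the bound of Saa3 was 163-fold without CD63 high replicate 1 and that of Slpi 179-fold without CD63 high replicate 2. The fibrinogen chains Fga, Fgb and Fgg rose together, with log2 fold changes of 3.23 (SE 0.34), 2.81 (SE 0.36) and 3.35 (SE 0.38). The chemokines Cxcl1 (5.55, SE 0.51), Ccl2 (4.35, SE 0.59), Ccl6 (5.30, SE 0.62) and Ccl9 (6.05, SE 0.54) rose too, as did the interleukin 1 receptor antagonist Il1rn (5.25, SE 0.63) and the adhesion molecule Icam1 (3.67, SE 0.44). Left-out libraries moved several of these: Fgg to 2.53 without CD63 high replicate 1, Ccl6 to 4.59 without CD63 high replicate 2, and Fgb, Ccl2, Ccl9 and Il1rn to 3.44, 5.61, 7.09 and 4.52 without CD63 low replicate 1, with 3.64, 5.38 and 7.24 for Ccl2, Ccl9 and Il1rn without CD63 low replicate 2. Slpi, Ccl2, Ccl6, Ccl9 and Il1rn were higher in CD63 high replicate 2 than in replicate 1, as the macrophage markers were, whereas Saa3, Fga, Fgb, Fgg, Cxcl1 and Icam1 were lower in replicate 2. Above 5 CPM, 18 of 20 acinar and 4 of 4 gamma cell markers were higher in replicate 2 too, and 7 of 8 duct cell markers lower. The direction between these libraries thus does not single out macrophages. Nfkbia, a target and inhibitor of NF-kB, rose from 60.8 ± 19.3 to 160 ± 55.8 CPM (mean ± SD, n = 2; log2 fold change 1.39), a call that ended without CD63 high replicate 1 (edgeR adjusted p 0.0504) and with the length and GC correction (0.0515). Tnfaip3, another such target, missed the threshold with an edgeR adjusted p of 0.0532, and DESeq2 called it (0.00543). The Y-linked genes Ddx3y and Eif2s3y had 531 to 1294 counts in every library and Xist 0, 0, 0 and 6 counts, for cells labelled as male.

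The first pattern is the rise of macrophage markers and of the interferon list. Macrophages or dendritic cells among the sorted cells would keep their markers in 1 ratio between the 2 CD63 high libraries. Of the 16 markers above 5 CPM, 100% were higher in replicate 2 than in replicate 1 (median log2 ratio 1.98, SD 0.477). Such cells in the sort would give this, but genes of a shared response can also move together. The interferon list did so, with 27 of 29 members lower in replicate 2, so such cells stay a hypothesis. Apoe, the most abundant marker, read 103 and 493 CPM in these libraries, none of the 23 tested markers is in another list, 5 of them exceeded 5 CPM in CD63 low cells, and a gate on a beta cell marker, of which the labels say nothing, would remove such cells. The interferon and antigen presentation genes ran the other way between the same libraries (median log2 ratio -0.43, SD 0.446, 29 genes), which argues against macrophages as the source of that list's rise. A response of the CD63 high beta cells themselves, or cells of another type, stays open and was not tested.

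The second pattern is the fall of maturity genes. The length and GC correction left the list's mean log2 fold change at -0.64, as before, which argues against that trend as the cause. If the most abundant transcripts had taken counts from these genes, the list would keep its level relative to the counts outside the 10 most abundant genes, but it lay lower there by a log2 difference of -0.72 (SE 0.072), against -0.68 relative to all counts. The 10 most abundant genes left 43.0% and 39.6% of counts in CD63 high and 36.5% and 44.3% in CD63 low libraries. Dilution of beta cells by other cells would lower Ins1 and Ins2 as much as the list. Relative to these 2 genes the list was lower by a log2 difference of -0.67 (SE 0.30). This lay inside the 95% bound of 1.29 that a t distribution gives for 2 against 2 libraries, so that test did not decide. Ins1 and Ins2 themselves changed by 0.06 and -0.06 (SE 0.23 each). Other beta cell lists, which dilution would lower too unless other cells express them, moved less than the maturity list (-0.65). The insulin granule list differed by 0.05, transcription factors by -0.28 and stimulus-secretion genes by -0.36 in mean log2 CPM. These lists share members with the maturity list, such as Slc30a8, Mafa and Glp1r. Which of their genes the other cells express was not tested, so these values do not decide either. Whether dilution, a lower expression of the maturity genes in CD63 high beta cells, or both lie behind the fall stays open. By fry the maturity list had an adjusted p of 0.104 for change in 1 direction and 0.0494 for change in either. With an estimated correlation, a test of little power at 2 residual degrees of freedom, the list was not called (camera adjusted p 0.297). Over the alternatives with the preset correlation its adjusted p ran from 3.38e-10 to 2.14e-05. Differences between sorts or animals that are not in the labels were not tested.

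The small upward shift of ribosomal protein and oxidative phosphorylation genes is the third pattern. Across genes, log2 fold changes fell with exon length (Spearman rho -0.244), and the trend differed between libraries of 1 group, with rho of -0.030 and -0.325 in the CD63 high and 0.015 and 0.291 in the CD63 low replicates 1 and 2. After the length and GC correction the mean log2 fold change was 0.13 instead of 0.26 for oxidative phosphorylation, which ended the call (camera adjusted p 0.120, 0.660 with an estimated correlation, range 2.23e-09 to 0.495 over the alternatives with the preset correlation), and 0.36 instead of 0.48 for ribosomal proteins (1.41e-08, range 6.73e-23 to 0.00240 likewise, and 0.514 with an estimated correlation), so length bias cannot be told apart from a difference between the groups. The larger gap between libraries of 1 group, that of CD63 low, was 0.37 for oxidative phosphorylation and 0.51 for ribosomal proteins, at or above the differences between groups (0.27 and 0.50). Spread between libraries may therefore account for both, and a difference tied to CD63 stays open.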
